A study of Haloferax mediterranei with 8 samples.

How the data were processed

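Total RNA of 16 *Haloferax mediterranei* cultures was isolated with RNeasy columns, labelled with Cy3 or Cy5 by Agilent's protocol for prokaryotic 2-colour arrays, and hybridised in pairs on 8 arrays of a custom Agilent design, per the labels' protocols. The media held 25% (w/v) salts at pH 7.3 with 10 g/l glucose, per the labels. All 8 arrays share 1 slide and 1 scan in the file headers, so neither could be fitted as a batch. The spots were read with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes. The deposited scanner files give for each spot the median pixel intensity and the median local background intensity in each dye, without normalization. They also hold processed intensities, background-subtracted and dye-normalised by Feature Extraction, and a log10 ratio of Cy5 over Cy3 made from them, per the file headers. On some own-design spots this ratio differs from that of the processed intensities, by up to 1.44, and it was not used.

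A deposited value table holds 15208 rows, 1 for each spot of the design's own probes. Set against the scanner values, it is a log2 ratio of Cy5 over Cy3, with correlations between 0.825 and 0.973 per array and medians between -0.0354 and 0.0321. Its values correlate at 0.968 to 1 with the loess-normalised log2 ratios computed here. The authors normalised these log2 values before they were deposited, as their closeness to the loess-normalised ratios shows; the method is not given in the sources used here. The table served as an alternative. The direction of every ratio comes from the dyes in the labels: Cy5 is channel 1 on all 8 arrays. The title of array 1 calls its second condition "Nitrogen as nitrogen source" where the channel's own label says nitrate, and the channel label was used.

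Each array holds 15744 spots, of which 536 are controls and 77 of these are negative controls. The design's own spots include 50 probes named hfx_c, with 10 spots each, which were left out of the ORF tests. The other 11703 probes belong to 3901 ORFs, 3 per ORF. Background was corrected with normexp and an offset of 50, on median foreground and median background intensity. A mean foreground intensity had been planned, but the files used here have the median. Log2 ratios were normalised by loess within each array, with control spots and spots with an outlier flag at weight 0. Outlier flags fell on 2004 of 121664 measurements of own-design spots, and these were left out; 0 own-design spots were saturated. A probe was tested if it was well above background, by Agilent's flag, in at least 4 of the 16 channels, which kept 11675 probes of 3896 ORFs. Spots of a probe were averaged, and then the probes of an ORF.

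The log2 ratios were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 1 loop design for all 8 arrays, a term for each condition and a dye effect for each ORF. This leaves 4 residual degrees of freedom for 3876 ORFs, and the moderated test adds 3.04. The 6 comparisons are contrasts of this fit. Adjusted p-values are Benjamini-Hochberg values within each comparison, and an ORF is called changed at an adjusted p under 0.05. Levels per culture are normalised log2 intensities of the separate channels after loess and Aquantile normalization, given as mean and SD over 4 cultures. They hold the dye effect, which the log2 change does not.

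An ORF not well above background with any probe on any array of a condition has only an upper bound there. In that case the fold is, on log2 levels, the mean of the brighter condition minus the mean, per channel, of the higher of 2 values: the lowest signal among probes well above background and the ORF's own signal. Contigs were tested as sets with camera, with a preset correlation of 0.01 and with an estimated correlation. These sets were chosen after the identifiers had been seen.

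The 37 gene lists fixed in advance, on nitrogen metabolism and related functions, could not be applied: 0 of them had a member, since the files pair the ORF identifiers with neither symbols nor products and the supplied gene table uses other locus tags. The rule for naming ORFs, also fixed in advance, takes those of adjusted p under 0.05 and at least 1 log2 unit with the highest and lowest change. Because the identifiers carry no gene names, it was shortened to 2 in each direction per comparison. Runs are sets of at least 3 consecutively numbered ORFs called in the same direction; whether numbers follow the position on the genome is not stated in the sources used here.

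On simulated log2 ratios with the residual spread of the real fit and 200 changed ORFs among 3896, the fit recovered 8.96% of ORFs changed 2-fold, 79.1% of those changed 4-fold and 97% of those changed 8-fold for starvation minus ammonium exponential, with 9 unchanged ORFs called. For ammonium stationary minus ammonium exponential it recovered 17.9%, 89.6% and 100%, with 5 unchanged ORFs called. For each ORF the simulated noise was independent and equal on all arrays. The real arrays had residuals from 0.3 to 0.73 log2 units (root mean square), so recovery from them can be lower. A count of 0 calls does not exclude large changes.

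The alternatives chosen before the data were examined were no background correction, Feature Extraction's processed intensities, median centring, Aquantile between arrays, other filters on dim probes, no dye effect, a separate-channel fit with the intraspot correlation, a replicate block, the brightest probe per ORF, a trended and robust prior, array weights, the authors' value table and leaving out each array in turn. Those added after the data had been seen were a background correction from the negative controls, centring each contig separately, a single-channel fit with the array as a random block, the same fit without 4 cultures whose contigs 3 and 4 stood high, and a fit without arrays 3 and 4.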

Results

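Transcript levels were measured in *Haloferax mediterranei*, a halophilic archaeon that grows in concentrated salt and can use either nitrate or ammonium as its nitrogen source. The series asked how its transcription depends on nitrogen availability. There were 4 conditions with 4 biological replicates each: cells with nitrate, cells with ammonium in exponential phase, cells with ammonium in stationary phase, and starved cells. Both nitrogen sources were supplied at 40 mM. The starved cells had been grown on ammonium to mid-exponential phase, washed, and kept for 48 h without nitrogen. The labels do not give the growth phase of the nitrate cultures.

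The 16 RNAs were hybridised in pairs, Cy5 against Cy3, on 8 arrays joined in a loop, with each condition in each dye on 2 arrays. Starvation was paired with nitrate on arrays 1 and 2 and with ammonium stationary on arrays 3 and 4. Ammonium exponential was paired with ammonium stationary on arrays 5 and 6 and with nitrate on arrays 7 and 8. Each of 3901 open reading frames (ORFs) had 3 probes, and 3896 ORFs were tested. The ORFs carry the array's own identifiers, a contig and a running number, and 0 of them matched a locus tag or symbol in the gene table supplied, so no ORF could be given a gene name or function. Contig 2 holds 3066 of the tested ORFs, contig 3 holds 439, contig 4 holds 267 and contig 5 holds 120. Here contig 4 stands for the identifiers that begin with ctg4.

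Signal over background differed between the conditions. Among the nitrate cultures 25.4% to 45.5% of the ORF spots were well above background, against 41.9% to 99.9% among the other 12 cultures. The median signal of the negative control spots lay between 821 and 6074 intensity units in the nitrate cultures and between 48 and 986 in the others. A level in nitrate that was not well above background on any array has only an upper bound, and a fold change against it is given as "at least". The number of arrays limits the precision: the median standard error (SE) of a log2 change was 0.297 for conditions that shared arrays and 0.343 for conditions compared only through the loop.

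In nitrate relative to exponential ammonium, the ORF ctg2_01765 rose 53.1-fold (log2 change 5.73 ± 0.53, SE; limma adjusted p = 0.00843). Its normalised log2 intensity was 17.21 ± 1.17 (SD, n = 4) with nitrate and 11.28 ± 0.56 (SD, n = 4) with exponential ammonium. ctg2_01764 rose as well (log2 change 4.83 ± 0.70, SE; limma adjusted p = 0.0266), but its probes differed, with log2 changes from 3.45 to 6.14, and its brightest probe gave the lowest of these. ctg2_02318 and ctg2_02317c were not well above background on any nitrate array. They were at least 24.7-fold lower (limma adjusted p = 0.00193) and at least 8.65-fold lower (limma adjusted p = 0.00318) with nitrate than in exponential ammonium, where their log2 intensities were 16.28 ± 0.42 and 14.77 ± 0.44 (SD, n = 4).

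These ORFs lay in runs of consecutive numbers that were called together. All 4 ORFs numbered 1764 to 1767 on contig 2 rose in nitrate, by 2.98 to 5.73 on the log2 scale. All 5 ORFs numbered 2143 to 2147 rose as well, by 2.40 to 4.25. The 4 ORFs numbered 2316 to 2319 were called lower, and so were 8 consecutive ORFs elsewhere on contig 2, with log2 changes between -2.99 and -2.11. On contig 4, 3 consecutive ORFs rose by 1.48 to 1.96. Altogether 113 ORFs changed, 43 higher and 70 lower in nitrate, all by at least 1 log2 unit. Contig 2 held 30 of the ORFs that rose and 63 of those that fell. In 18 of the 113, the condition with the lower level was not well above background on any array.

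The count depended on the model and on single arrays. A fit of separate channels called 719 ORFs, 110 of them among the 113. Leaving out arrays 1 to 8 in turn gave 10, 13, 15, 242, 66, 24, 8 and 0 called ORFs. The majority of lower ORFs turned without arrays 1, 2 and 3 (6 higher and 4 lower, 7 and 6, and 10 and 5), with a replicate block (37 and 25) and with only probes well above background in all channels (92 and 71). With 1 array left out, the log2 change of ctg2_01765 stayed between 4.82 and 6.32, with the call lost without array 8 (adjusted p = 0.0684), and that of ctg2_01764 between 3.79 and 5.60, with the call lost for 6 of the 8 arrays and with the replicate block (adjusted p = 0.058). ctg2_02318 and ctg2_02317c also lost their calls without array 8 (adjusted p = 0.0579 for both).

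Starvation was set against exponential ammonium through the loop. ctg2_01765 rose 41.4-fold (log2 change 5.37 ± 0.62, SE; limma adjusted p = 0.018), to 16.90 ± 0.47 (SD, n = 4) in starved cells. ctg2_02146 rose 40.5-fold (5.34 ± 0.58, SE; limma adjusted p = 0.018), from 11.45 ± 0.68 to 16.93 ± 0.42 (SD, n = 4). ctg2_02318 fell 65.7-fold (-6.04 ± 0.40, SE; limma adjusted p = 0.00481), to 10.63 ± 0.52, and ctg2_02317c fell 28-fold (-4.81 ± 0.40, SE; limma adjusted p = 0.00778), to 10.47 ± 0.30 (SD, n = 4).

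The 4 ORFs numbered 1764 to 1767 all rose after starvation, by 4.06 to 5.37 on the log2 scale, and the 5 ORFs numbered 2143 to 2147 all rose by 3.71 to 5.34. A run of 9 ORFs with low numbers on contig 2 rose by 2.03 to 2.76. The longest runs went down. A run of 12 ORFs of contig 2 had log2 changes between -3.51 and -2.95, and 11 ORFs that follow it after a gap of 1 number had changes between -4 and -3.21. The mean level of these 11 was 12.62 ± 0.27 in starved cells and 16.64 ± 0.35 in exponential cells (SD, n = 4). Another run of 9 ORFs had changes between -2.93 and -1.74. In all, 264 ORFs changed, 88 higher and 176 lower after starvation, a majority that turned without array 1 (23 higher and 14 lower). Contig 2 held 76 of the ORFs that rose and 159 of those that fell, contig 3 held 8 and 7, contig 4 held 3 and 8, and contig 5 held 1 and 2.

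The median log2 change was 0.55 on contig 3, 0.40 on contig 4 and -0.03 on contig 2. With a preset correlation of 0.01 between ORFs, contig 3 as a set stood above the other ORFs (camera, adjusted p = 2.78e-05), and with an estimated correlation it did not (adjusted p = 0.553). Starvation replicate 4 and exponential replicate 3, on opposite sides of this comparison, had contig 3 medians 0.39 and 0.38 above their contig 2 medians, while the difference was between -1.13 and -0.71 in the other 6 cultures. No array held both conditions. The separate-channel fit called 962 ORFs, 255 of them among the 264, and leaving out arrays 1 to 8 in turn gave 37, 2, 8, 200, 1, 0, 205 and 145. With 1 array left out, the log2 change of ctg2_02318 lay between -6.40 and -5.69, that of ctg2_01765 between 4.77 and 5.85, that of ctg2_02146 between 4.81 and 5.89 and that of ctg2_02317c between -5.14 and -4.45. All 4 lost their calls without array 6, the last 3 also without arrays 2 and 5, and ctg2_01765 without array 3 as well (largest adjusted p 0.055 for ctg2_02318, 0.0746 for ctg2_01765 and ctg2_02146, and 0.0665 for ctg2_02317c). With a replicate block the comparison had 2 called ORFs, and ctg2_01765, ctg2_02146 and ctg2_02317c were not called (adjusted p = 0.0932, 0.0883 and 0.0657).

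**Figure D1:**
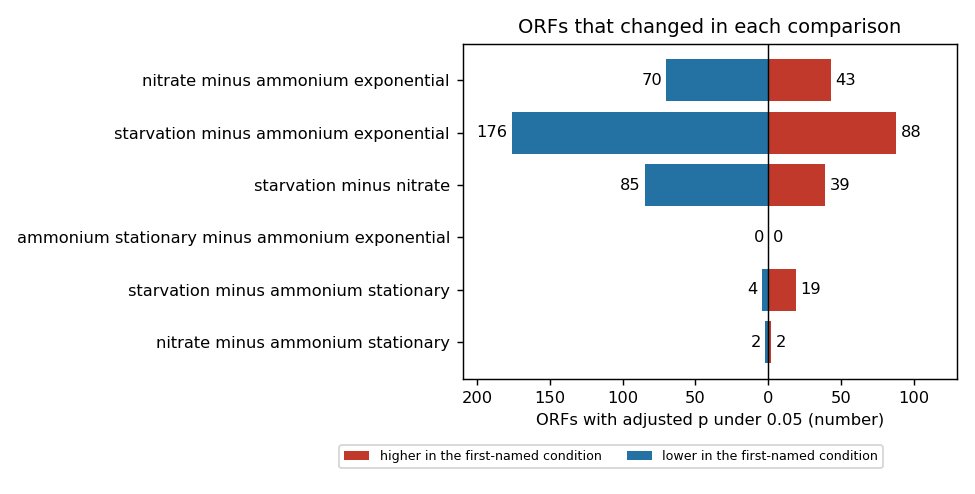
ORFs with a limma adjusted p under 0.05 in each of the 6 comparisons (horizontal axis, number of ORFs), with those higher in the first-named condition to the right and those lower to the left. Starvation minus ammonium exponential has the longest bars, 88 higher and 176 lower, and ammonium stationary minus ammonium exponential has 0.

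**Figure D2:**
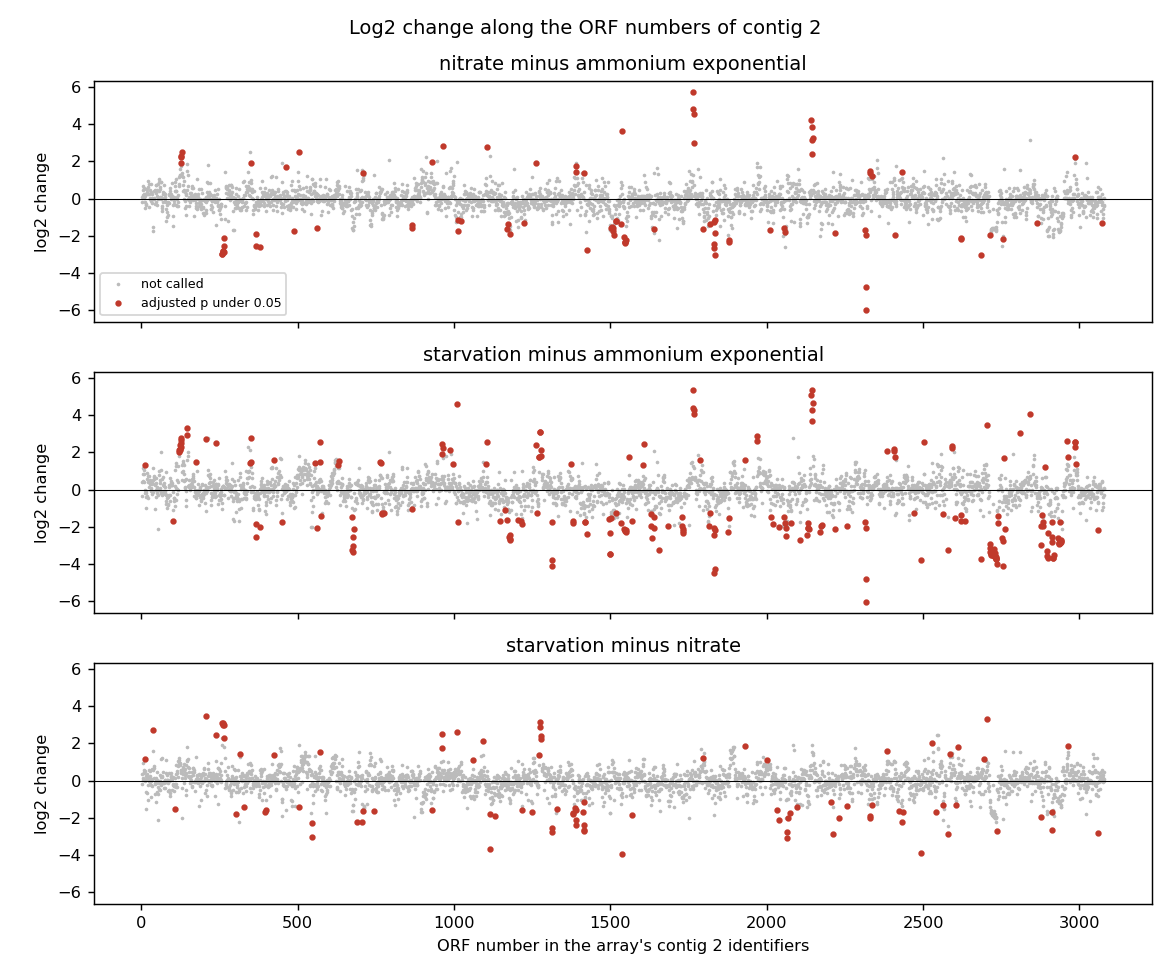
Log2 change of each ORF of contig 2 (vertical axis) against its number in the array's identifiers (horizontal axis) for 3 comparisons, with ORFs of adjusted p under 0.05 as larger red points. Many called ORFs stand in clusters of consecutive numbers, such as 1764 to 1767 and 2143 to 2147 upwards and 2316 to 2319 downwards in the upper panels, and others stand alone. Over all contigs, 59 of 113, 166 of 264 and 47 of 124 called ORFs, from the top panel down, had a neighbour called in the same direction.

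Starvation was set against nitrate directly on arrays 1 and 2. ctg3_00338c was higher in starved cells (log2 change 4.16 ± 0.36, SE; limma adjusted p = 0.00782), at 14.74 ± 0.52 against 10.80 ± 0.37 with nitrate (SD, n = 4). It was above background on 3 of the 4 nitrate arrays, and its probes ranged from 2.58, for the brightest, to 5.91, so the size of the change is uncertain. ctg2_00207c was at least 7.33-fold higher in starved cells (limma adjusted p = 0.0133), since it was not well above background on any nitrate array. ctg3_00100c was 20-fold lower after starvation (-4.32 ± 0.32, SE; limma adjusted p = 0.00342), and ctg2_01537c was 15.2-fold lower (-3.93 ± 0.23, SE; limma adjusted p = 0.00179). The levels of ctg2_01537c were 14.32 ± 1.59 in starved cells and 17.79 ± 0.45 with nitrate (SD, n = 4), and its call was lost when the dye effect was left out of the model (adjusted p = 0.0509).

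In this comparison 124 ORFs changed, 39 higher and 85 lower in starved cells. A run of 5 ORFs numbered 259 to 263 on contig 2 rose by 3.01 to 3.11 relative to nitrate, and 4 ORFs numbered 1275 to 1278 rose by 2.23 to 3.12. The mean nitrate level of the latter run was 10.64 ± 0.13 (SD, n = 4). That is below the 11.46 of ctg2_00207c, which was not well above background on any nitrate array. The size of this run's change is therefore uncertain. On contig 3, 5 ORFs numbered 99 to 103 were lower, with log2 changes between -4.32 and -1.72. On contig 4, the 3 ORFs numbered 142 to 144 were lower, between -2.13 and -1.23. The runs 1764 to 1767 and 2316 to 2319 were called against exponential ammonium both in nitrate and in starvation. Between starvation and nitrate they had mean log2 changes of 0.01 and -0.08, with 0 called ORFs. In the run 2316 to 2319, ctg2_02318 and ctg2_02317c were not well above background on any nitrate array. Their nitrate levels have only an upper bound, so the -0.08 does not show that the conditions were alike.

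Of the ORFs of contig 5, 7 were lower and 0 higher after starvation relative to nitrate, with a median log2 change of -0.48. As a set, contig 5 stood below the other ORFs with a preset correlation (camera, adjusted p = 2.14e-08) but not with an estimated correlation (adjusted p = 0.225). In 21 of the 124 ORFs the lower condition was not well above background on any array. Separate channels gave 528 called ORFs, 117 of them among the 124. Leaving out arrays 1 to 8 in turn gave 3, 7, 21, 142, 27, 56, 82 and 6. The log2 change of ctg3_00100c stayed between -4.73 and -3.75 with its call kept, whereas ctg3_00338c lost its call without array 1 (adjusted p = 0.0562) and ctg2_00207c without arrays 1, 2 and 8 (adjusted p = 0.118, 0.0993 and 0.0695).

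**Figure D3:**
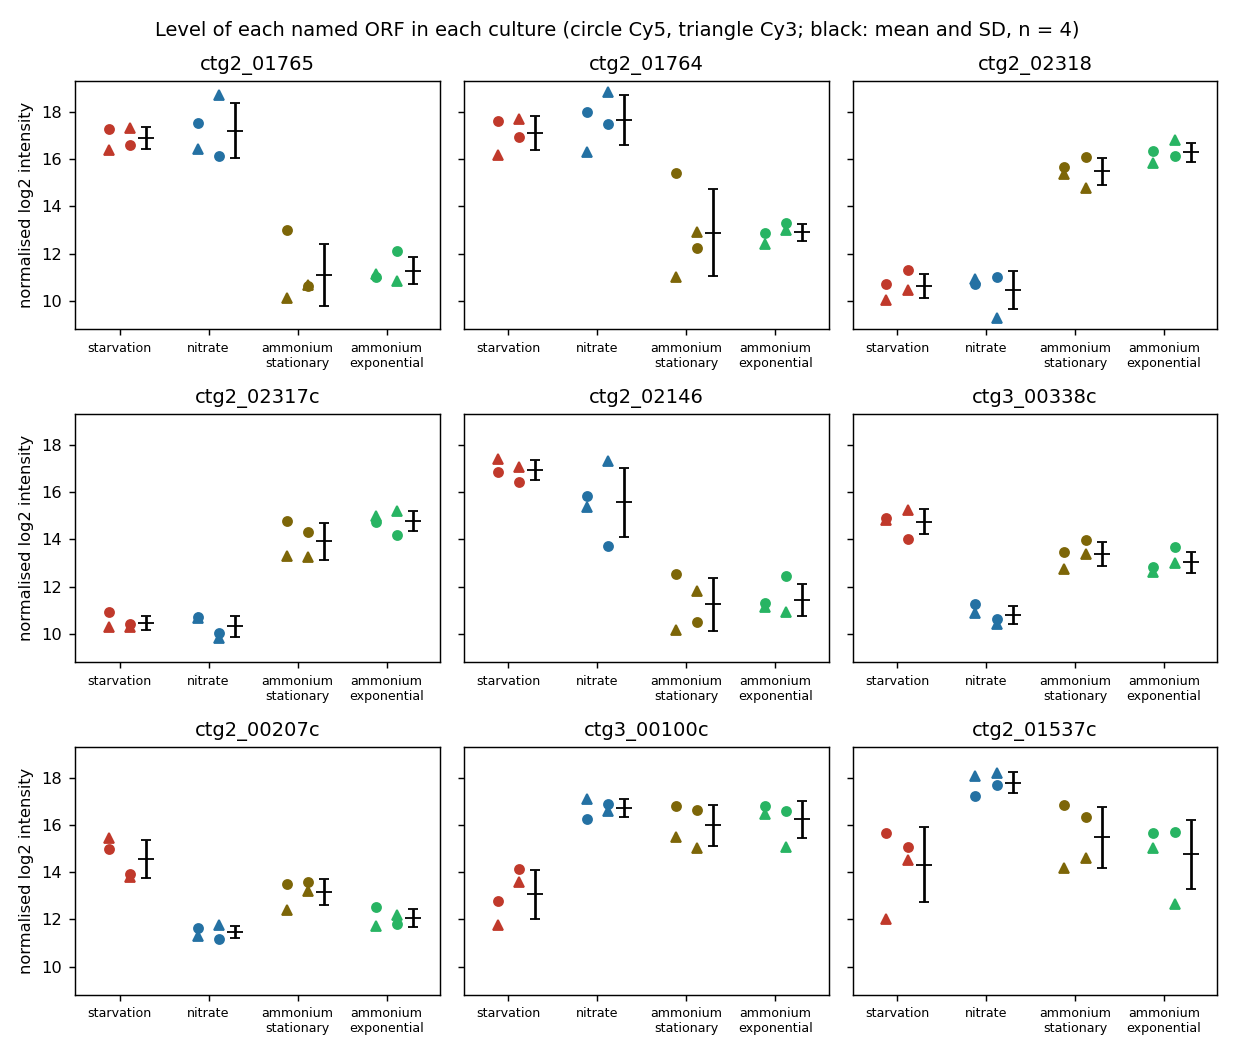
Normalised log2 intensity (vertical axis) of each ORF named in the text in each culture, by condition, with circles for Cy5, triangles for Cy3, and black bars for the mean and SD of 4 cultures. ctg2_01765 lies near 17 in starvation and nitrate and near 11 in both ammonium conditions, and ctg2_02318 shows the opposite order; its nitrate values, and those of ctg2_02317c and ctg2_00207c, were not well above background.

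Between stationary and exponential ammonium cultures, limma on the log ratios called 0 of 3896 ORFs, with 735 at an unadjusted p under 0.05 and a smallest adjusted p of 0.065. The separate-channel fit of limma called 435 ORFs, 72 higher and 363 lower in stationary cultures. No ORF is therefore named. Some runs that fell after starvation had low stationary means too: the 4 ORFs numbered 2897 to 2900 on contig 2 had a mean log2 change of -3.16 in stationary relative to exponential cells, with 0 of 4 called. Among the runs that rose in nitrate and starvation, 1764 to 1767 and 2143 to 2147 had mean changes of -0.14 and 0.51, whereas 126 to 129, called in nitrate and for 3 of its 4 ORFs in starvation, had a mean change of 1.29, with 0 called.

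The median log2 change between stationary and exponential cultures was 0.67 on contig 3, 0.62 on contig 4 and -0.07 on contig 2. As sets, contigs 3 and 4 stood above the other ORFs with a preset correlation (camera, adjusted p = 9.36e-12 and 1.76e-09) but not with an estimated correlation (adjusted p = 0.396 for both). Only 2 of the 4 stationary cultures carried this shift: the contig 3 median minus that of contig 2 was 0.33 and 0.38 in replicates 3 and 4, and -0.53 and -0.42 in replicates 1 and 2. Arrays 5 and 6, the direct pair of this comparison, mirrored each other across ORFs (r = -0.66), but their mean was negatively correlated with the estimate through the rest of the loop (r = -0.24 across 3876 ORFs, which are not independent replicates). Arrays 5 and 6 set stationary replicates 3 and 4, with the shift, against exponential replicates 1 and 2, without it. The rest of the loop held stationary replicates 1 and 2 without it and exponential replicate 3 with it. Growth phase and the difference between these cultures therefore cannot be told apart in these 2 correlations. Without array 3 the fit called 20 ORFs, and without each of the other arrays 0, but without both arrays 3 and 4, which removes stationary replicates 1 and 2, it called 1028, 603 higher and 425 lower in stationary cultures. The stationary cultures left there were replicates 3 and 4, both with the shift, so the shift is part of the difference called.

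**Figure D4:**
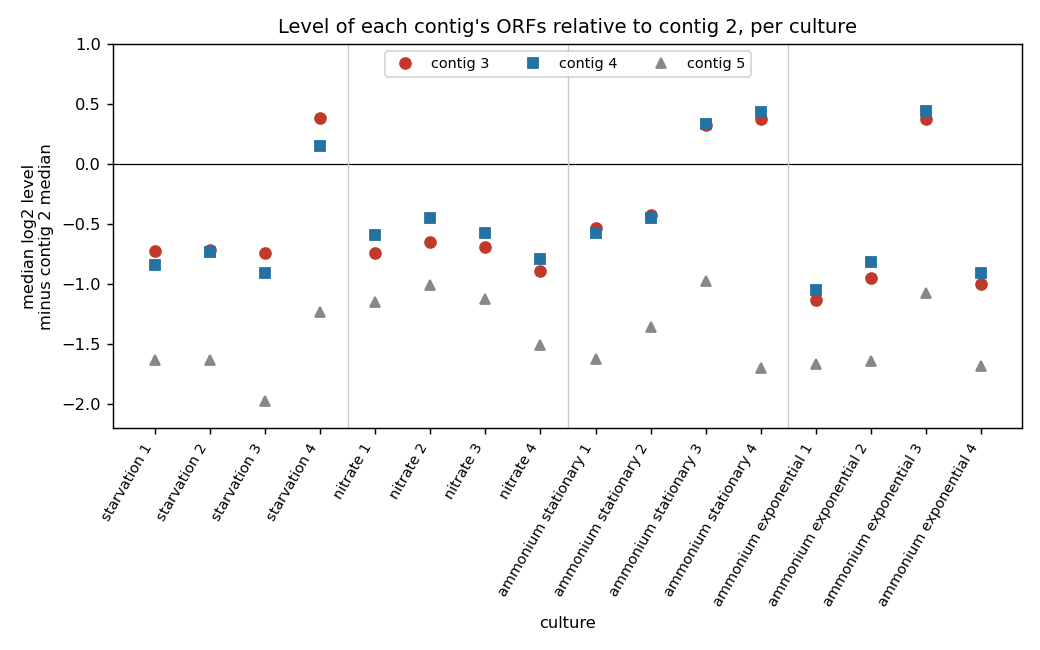
Median log2 level of the ORFs of contigs 3, 4 and 5 minus that of contig 2 (vertical axis) in each of the 16 cultures (horizontal axis, by condition and replicate). Contigs 3 and 4 lie above 0 in starvation 4, stationary 3 and 4 and exponential 3, and below 0 in the other 12 cultures.

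Starvation relative to stationary ammonium again had ctg2_01765 highest, 48.4-fold (log2 change 5.60 ± 0.53, SE; limma adjusted p = 0.00739), from 11.11 ± 1.30 to 16.90 ± 0.47 (SD, n = 4). ctg2_02146 rose 42.3-fold (5.40 ± 0.50, SE; limma adjusted p = 0.00703). ctg2_02318 fell 32.5-fold (-5.02 ± 0.34, SE; limma adjusted p = 0.00344) from 15.48 ± 0.57 in stationary cells, and ctg2_02317c fell 13.2-fold (-3.72 ± 0.35, SE; limma adjusted p = 0.00703). The 5 ORFs numbered 2143 to 2147 were all called, with a mean log2 change of 4.12, and so were 3 of the 4 numbered 1764 to 1767.

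Of 23 ORFs that changed, 19 were higher and 4 lower in starved cells, and 21 of them were on contig 2. Without the direct arrays 3 and 4 the majority turned, with 53 higher and 285 lower. The stationary cultures left there were replicates 3 and 4, both with high contigs 3 and 4, so that shift is part of the difference. Arrays 3 and 4 mirrored each other less than the other pairs (r = -0.26 across 3876 ORFs). Their mean had a correlation of 0 with the estimate through the rest of the loop. Array 4 had the largest residual of the fit, 0.73 log2 units (root mean square). The separate-channel fit called 270 ORFs, 141 higher and 129 lower, including all 23. Leaving out arrays 1 to 8 in turn gave 14, 13, 0, 22, 8, 4, 21 and 15 called ORFs. The log2 change of ctg2_01765 then lay between 5.19 and 6.32, that of ctg2_02146 between 4.61 and 6.22, that of ctg2_02318 between -5.30 and -4.84 and that of ctg2_02317c between -4.14 and -3.35. Without array 3 all 4 named ORFs lost their calls (adjusted p = 0.147 for ctg2_01765 and 0.0855 for the other 3), and without array 6 ctg2_01765 (0.0753), ctg2_02146 and ctg2_02317c (0.0669 for both) did.

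Nitrate relative to stationary ammonium, compared only through the loop, gave 4 called ORFs. ctg2_01765 was 62.1-fold higher with nitrate (log2 change 5.96 ± 0.62, SE; limma adjusted p = 0.0338) and ctg2_01537c 10.3-fold higher (3.36 ± 0.27, SE; limma adjusted p = 0.0093). ctg2_02318 was at least 14.2-fold lower (limma adjusted p = 0.0093) and ctg2_02317c at least 4.75-fold lower (limma adjusted p = 0.0354), both not well above background on any nitrate array. With 1 of the 8 arrays left out, ctg2_01765, ctg2_01537c and ctg2_02317c each lost the call for 6 arrays and ctg2_02318 for 5, with largest adjusted p of 0.264, 0.189, 0.3 and 0.189. The log2 change of ctg2_01765 then lay between 5.35 and 6.44 and that of ctg2_01537c between 3.21 and 3.55. Under the other settings ctg2_02317c lost it in 6, ctg2_01537c in 4, ctg2_01765 in 3 and ctg2_02318 in 1, with largest adjusted p of 0.0909, 0.287, 0.0787 and 0.0548. Separate channels gave 251 called ORFs, 178 higher and 73 lower. Leaving out arrays 1 to 8 in turn gave 1, 0, 0, 24, 0, 0, 6 and 0.

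Many of the ORFs called in nitrate were also called in starvation, both relative to exponential ammonium. Among the 3876 ORFs measured on every array, 20 were higher and 40 lower in both, and 0 went in opposite directions. Independent lists would share 0.976 and 3.18, and 100 simulated loops without any effect shared a mean of 0, a value of little weight since such loops called a mean of only 0.06 and 0.08 ORFs. The log2 changes of the 2 comparisons had r = 0.62 across ORFs, against 0.58 in the simulated loops, and their covariance was 0.422 against 0.101 simulated. When they were estimated from separate arrays with different exponential cultures, r was 0.06, and of 57 and 288 called ORFs 7 were higher and 11 lower in both. The 20 ORFs higher in both include ctg2_01765 and ctg2_02146, and the 40 lower in both include ctg2_02318 and ctg2_02317c.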

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

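The tests of the sample labels, the growth phase and the negative-control background and the fit without arrays 3 and 4 in this part were chosen after the results they bear on had been seen; the tests of an even added signal and of the widened spread were fixed before their results were known. Of 56 groups of 4 cultures screened for a single culture far from the others, 7 were picked out, where chance gives 2.8 (about 1 in 20).

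In 4 cultures of 3 conditions the ORFs of contigs 3 and 4 stood high as a whole. The contig 3 median minus the contig 2 median was 0.39 in starvation replicate 4, against -0.74 to -0.71 in the other starved cultures, and for contig 4 it was 0.15, against -0.90 to -0.73. In exponential replicate 3 it was 0.38 for contig 3, against -1.13 to -0.95, and 0.45 for contig 4, against -1.05 to -0.82, while contig 5 stood at -1.08, against -1.68 to -1.64. These 5 values lay farther from their group than Dixon's limit. Stationary replicates 3 and 4 had contig 3 values of 0.33 and 0.38, against -0.53 and -0.42 in replicates 1 and 2.

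An even added signal such as DNA in those RNAs would raise contig 2 ORFs of similar level as much as those of contigs 3 and 4. The matched contig 2 ORFs rose by at most 0.1 of the rise of contigs 3 and 4 in any of the 4 cultures. Loess and centring on the contig 2 median hold this share near 0, because they take out shifts common to all contigs. Such a signal is therefore not excluded, but alone it would not lift contigs 3 and 4 above matched contig 2 ORFs. Wrong sample labels would put the cultures nearer to another condition on contig 2, but 4 of the 4 lay nearest to their own, although stationary replicate 3 was practically tied (root mean square distance 0.69 against 0.69) and stationary replicate 2, which lacks the shift, lay nearer to nitrate (0.66) than to its own condition (0.69). Exponential replicate 3 lay at 0.68 from its own condition and 0.76 from the next, where the other exponential cultures lay at 0.32 to 0.41 from theirs. Wrong labels are therefore not excluded for every culture. Stationary growth phase as the sole cause is excluded, since 2 of the 4 stationary cultures had the shift and 2 lacked it, and an exponential culture had it. A difference between the cultures that the labels do not record, such as in the copy number of these contigs, may be the source and was not tested. The labels name no culture batch to set against it.

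For stationary against exponential ammonium, where the log ratios gave 0 calls, the 4 cultures may hide differences by widening the spread. A single-channel fit with the array as a random block called 414 ORFs with all 16 cultures and 912 without those 4. The median SE was 0.29 in both fits although the second had fewer cultures, and the SD of the log2 changes across ORFs went from 0.71 to 0.84. This goes with the explanation but does not isolate it, since the same change also removes the shift of contigs 3 and 4 from the difference itself, and since the change from log ratios to single channels alone moved the count from 0 to 414. The log-ratio fit without arrays 3 and 4 keeps 3 of the 4 cultures and called 1028. Its only stationary cultures are replicates 3 and 4, both with the shift, so it too removes the spread that the shift makes among stationary cultures. The shift also becomes part of the difference that it calls. That fit therefore cannot tell whether the 4 cultures keep the count low, and the explanation stays open.

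The negative controls of nitrate replicate 2 had a median of 6074 intensity units, against 821 to 1185 in the other nitrate cultures. Background of this kind could compress differences that involve nitrate. Correcting each channel by its own negative controls stretched the log2 changes of nitrate minus ammonium exponential 1.03 times as much as those of starvation minus ammonium exponential over all ORFs, which argues against a large compression, but the calls went from 113 to 158 against 264 to 265, so a small one stays open. Nor do the nitrate calls rest on background alone, since 110 of the 113 ORFs kept their call under that correction. No biological explanation was tested, because a negative control has no target in the cells.

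The nitrate replicate 3 level of ctg2_02318 was 9.29, below the 10.72 to 11.01 of the other nitrate cultures, and none of these values was well above background. The 50 hfx_c probes, which belong to no comparison of the report and whose target is not given in the sources used here, gave median signals 1.07 to 24.5 times those of the negative controls in the 16 channels, with a median of 3.15. The lowest ratios were those of nitrate, 1.07 to 1.49, against 2.85 to 20.9 in starvation. In starvation minus nitrate, 18 of the 50 were called lower and 0 higher, but with nitrate signals this near to background these calls cannot be read as a change in the cells.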

How the results depend on the processing

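The negative-control correction, the contig centring, the single-channel fits with an array block and the fit without arrays 3 and 4 were chosen after the results had been seen. For the named ORFs, 417 of 490 values under alternatives other than Aquantile kept direction and side of the threshold, 73 kept the direction but not the call, and 0 reversed. These ORFs were chosen for the largest changes on the same arrays, so a reversal was unlikely from the start. The calls kept ranged from 20 of 20, as with the authors' value table, to 8 of 20 without array 6. The comparisons below are in the order nitrate minus exponential, starvation minus exponential, starvation minus nitrate, stationary minus exponential, starvation minus stationary and nitrate minus stationary, with 113, 264, 124, 0, 23 and 4 called ORFs as reported. Separate channels gave 719, 962, 528, 435, 270 and 251, and the single-channel fit with an array block 700, 1030, 500, 414, 255 and 253. Without the 4 cultures with high contigs 3 and 4 that fit gave 1073, 1431, 631, 912, 176 and 167. Without arrays 3 and 4 the log-ratio fit, with fewer arrays and no closed loop, gave 370, 136, 203, 1028, 338 and 690. Array weights, whose estimation stopped before convergence, moved the first 3 to 789, 542 and 475 and starvation minus stationary to 38. Only probes well above background in all channels, which leaves 1187 ORFs, gave 171 for starvation minus exponential, 54 for stationary minus exponential, 11 for starvation minus stationary and 19 for nitrate minus stationary; it turned the split of nitrate minus exponential from 43 higher and 70 lower to 92 and 71, and that of starvation minus nitrate from 39 and 85 to 22 and 121. Without a dye effect stationary minus exponential had 6 and nitrate minus stationary 7. The trended and robust prior gave 57 for starvation minus nitrate. For nitrate minus stationary, median centring gave 0, the brightest probe 2, the trended prior 2 and contig centring 7, and both no background correction and the processed signals gave 2 higher and 1 lower. The majority also changed side for starvation minus stationary without arrays 3 and 4, with 53 higher and 285 lower against 19 and 4. The cause of these changes was not tested. With 1 array left out, the counts ranged from 0 to 242, 0 to 205, 3 to 142, 0 to 20, 0 to 22 and 0 to 24.

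The labels do not say whether replicate numbers pair the cultures, and the values showed no clear pairing. Of 24 pairs of same-numbered cultures from different conditions, 12 had correlated deviations from their condition means (r over 0.1, range -0.53 to 0.51), and for 5 of 16 cultures the best match had the same number. The median r was 0.07 for pairs with the same number and -0.02 for pairs with different numbers. With a replicate block, of which 2 terms could be estimated and which leaves 2 residual degrees of freedom, the counts were 62, 2, 38, 0, 34 and 2, and 37 of the 62 were higher in nitrate.

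Aquantile between arrays leaves the log ratios as they are, so it tested nothing. Slide or scan as a block and the alternatives for gene lists were not run, since there was 1 slide, 1 scan and no list with a member. Signal over background limits the nitrate levels most: 1.35 to 2.90 times the negative controls, against 2.97 to 79.8 in the other cultures.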

Other observations

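The tests of neighbouring ORFs in this part were chosen after the runs had been seen; the regroupings of the cultures were fixed before.

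The long runs of contig 2 that fell after starvation had mean levels in nitrate and stationary ammonium between those of starvation and exponential ammonium. The 11 ORFs numbered 2726 to 2736 had mean log2 levels of 16.64 ± 0.35 in exponential ammonium, 14.86 ± 1.16 in nitrate, 14.10 ± 0.84 in stationary ammonium and 12.62 ± 0.27 in starvation (SD, n = 4). In nitrate minus exponential 0 of the 11 were called, with a mean log2 change of -1.60. The 8 ORFs numbered 258 to 265 had their lowest mean level in nitrate: 12.73 ± 0.24 in nitrate, against 15.07 ± 0.48 in starvation, 14.69 ± 0.90 in stationary and 15.55 ± 0.43 in exponential cultures. Of these, 8 were called against exponential, 6 against starvation and 0 against stationary cultures. The 4 ORFs numbered 1275 to 1278 were highest in starvation, at 13.25 ± 0.49, against 10.64 ± 0.13 in nitrate, 11.38 ± 0.43 in stationary and 10.99 ± 0.19 in exponential cultures.

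In starvation minus ammonium exponential, 119 pairs of consecutive ORFs were called in the same direction, against a mean of 10.5 and a highest of 23 in 10000 shuffles of the calls within each contig (p = 1e-04, one-sided permutation test, the smallest these shuffles can give). The log2 changes of consecutive ORFs correlated at 0.74 for 2369 pairs with the same suffix in their identifiers and 0.533 for 1511 pairs with different suffixes. In stationary minus exponential, with 0 called ORFs, these correlations were 0.77 and 0.64, so they do not depend on a called response. The correlations pool all contigs without centring each. Median changes in that comparison were 0.67 on contig 3, 0.62 on contig 4 and -0.07 on contig 2. Shifts of whole contigs can therefore add to the correlations, whereas the shuffles were made within contigs. Placement of the spots is an unlikely source, because the slide rows of consecutive ORFs correlated at -0.00395. A candidate explanation is that numbers follow gene order and that neighbours share transcripts or regulation, which the identifiers alone do not establish.

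Other splits of the same 8 cultures, with the arrays kept, were fitted for each comparison, leaving out 1 or 2 of 35 splits that the loop could not estimate. In 4 comparisons only 1 split, the real one, gave as many calls: nitrate minus exponential (113, highest other 0, 34 splits), starvation minus exponential (264, highest other 0, 33 splits), starvation minus nitrate (124, highest other 0, 34 splits) and starvation minus stationary (23, highest other 1, 34 splits). That is a share of 0.0294 or 0.0303, the smallest that these splits can give. Taking each comparison alone, without adjustment for the 6 comparisons, chance is unlikely for these 4 but not excluded. For nitrate minus stationary chance stays open, since 2 of 33 splits gave at least 4 calls, the real one and one with 252 that had stationary replicates 1, 3 and 4 and nitrate replicate 1 on the same side. For stationary minus exponential the count says nothing about chance: the real split gave 0, so all 34 splits reach it by construction. The highest other split gave 581. It exchanged stationary replicate 2 with exponential replicate 3, and the split with 252 exchanged stationary replicate 2 with nitrate replicate 1. Both point to a structure of the cultures other than the condition, with stationary replicate 2 in common. The split with 581 also put all 3 cultures with high contigs 3 and 4 on the same side, which the real split does not. These 2 features cannot be told apart there. The split with 252 had 2 such cultures on the same side. The real split keeps these together as well and gave 4 calls, so this feature alone does not account for the 252. Stationary replicate 2 was on array 4, which had the largest residual (0.73). On contig 2 it lay nearer to nitrate (0.66) than to its own condition (0.69).

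The starvation response relative to exponential ammonium overlapped with those relative to nitrate and to stationary ammonium, with starved cultures shared. With starvation minus nitrate, 19 ORFs were higher and 20 lower in both (0.908 and 3.91 for independent lists). Simulated loops without effects shared 0.01, but they called a mean of only 0.11 and 0.08 ORFs. Estimates from separate arrays called 38 and 288 ORFs, 7 higher and 10 lower in both. Across ORFs r was 0.65, against 0.58 simulated and 0.34 from separate arrays, and the covariance was 0.459 against 0.102 simulated. With starvation minus stationary, 18 were higher and 4 lower in both (0.431 and 0.182 for independent lists, 0.02 in simulated loops that called 0.1 and 0.08). Separate arrays called 12 and 1 ORFs, too few to compare. Here r was 0.62, against 0.58 simulated and 0.51 from separate arrays, and the covariance was 0.332 against 0.101 simulated.

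The only ORF not named by contig and number, bgah, had 1 probe well above background in 14 of the 16 channels and 2 probes in 0. The signal of the bright probe, not normalised, was 5936 to 29687 intensity units on arrays 1 to 4 and 599.5 to 5921 on arrays 5 to 8. Each of arrays 1 to 4 held a starved culture and none of arrays 5 to 8 did. These ranges cover both channels of each array, however. Nitrate and stationary cultures, which were on both sets of arrays, thus also gave higher signals on arrays 1 to 4. Starvation alone therefore does not account for the difference, and its source was not tested.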
